A study of Mus musculus with 4 samples.

How the data were processed

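Total RNA (300 ng per sample) of sorted mouse bone marrow-derived cells was amplified with random hexamers, labelled with biotin and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The deposited values are log2 expression values per probe set, made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA by definition subtracts background, brings all arrays to one distribution and summarises the probes of a probe set. It therefore compresses differences of dim genes and cannot show a change in total RNA per cell. The level at which RMA was run is not given in the sources used here. No detection calls, scan dates or batches were in the values used here, so batches were not tested.

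Probe sets were named with the platform annotation. Of 35556 probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 12146 had none listed, and 21698 of the single-symbol probe sets matched a RefSeq gene table (GRCm38.p6) by gene ID, with 0 symbols updated. Probe sets with several symbols were not named. A gene with more than 1 probe set (999 of 19938 genes) was represented by the one with the highest mean over the 4 arrays. Genes entered when at least 2 of the 4 arrays lay above that array's 30th percentile of all probe sets, which left 14995. Positions are not given, because the files name no genome build.

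The groups were 2 GM-CSF M1 and 2 M-CSF M2 arrays, and differences are M1 minus M2. Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 2 residual and 4.17 prior degrees of freedom), with Benjamini-Hochberg adjustment at 0.05, and a further count asked for an absolute log2 difference of at least 1. Folds are powers of the log2 difference. Shifts of 36 gene lists were tested with camera at its preset inter-gene correlation of 0.01 for lists of at least 5 tested members, with camera's estimated correlation and fry as alternatives. With the preset correlation, camera takes its degrees of freedom from the number of genes tested, so its small p-values do not rest on many arrays. With 2 residual degrees of freedom an estimated correlation is itself imprecise. That version of camera also takes its p-value from these 2 degrees of freedom, so a list may fail it whatever its correlation. The chemokine (-0.038) and MHC class II presentation (-0.034) lists had estimated correlations below the preset 0.01 and an adjusted p of 0.291 with it. Failing it therefore does not by itself show that correlation between genes explains a shift. Other called lists had estimates above the preset, such as interferon response (0.973), cholesterol synthesis (0.508), glycolysis (0.329) and dissociation stress (0.281). For those the preset may understate the correlation, and fry did not call them (fry adjusted p = 0.611, 0.179, 0.0522 and 0.192). Fry still called the interleukin-1 and inflammasome list (estimate 0.249, fry adjusted p = 0.0351). Many members belong to more than 1 list, so the lists are not independent. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

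The groups, tests, gene lists, other settings and rule for named genes were fixed before the data were examined. The rule names the 12 genes with the largest difference in each direction among those past the threshold whose arrays do not overlap between groups, the genes of the sort gate, up to 4 members of each list with the largest absolute difference, and Csf1r, Csf2ra, Csf2rb, Nos2, Arg1, Mrc1, Zbtb46 and Flt3 where measured. A further gene of the rule is not reported here. Predicted genes, pseudogenes and olfactory or vomeronasal receptors were passed over in the first part. It gave 152 genes, and the text leaves some out. Genes named outside it are said to have been chosen after their values were seen.

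The olfactory receptor genes (1027 on the array, 212 past the filter) served as a background reference chosen after the data were seen, with a mean 95th percentile of 5.90 over the arrays.

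The other settings fixed then were no filter and a stricter filter (50th percentile), quantile normalization, centring on array medians, the mean of all probe sets of a gene, trended and robust variances, a replicate block, an adjusted p of 0.01, an unmoderated statistic, other set tests, and leaving out each array in turn. Array weights per group were added after seeing the data. When an array was left out, the genes tested were kept as in the fit of 4 arrays. At first the dim filter was applied again to the 3 arrays left, and this was changed after the result was seen, because genes bright in a single group then dropped out. Both versions are given with the other settings. A group left with 1 array was assumed to vary like the other.

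The fit was tested on simulated data for the GM-CSF against M-CSF comparison with 14995 genes, of which 50 were changed at each size. It recovered 2% of changes of 0.5 on the log2 scale, 66% of changes of 1, 96% of changes of 2 and 100% of changes of 4, and called 139 genes, 7 of them unchanged ones. In this simulation, differences well under 2-fold were mostly not detected. It changed few genes and gave both groups the same spread, so its recovery need not hold for the data. There 635 of the 1605 genes called differed at least 2-fold, so many smaller differences passed too.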

Results

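Gene expression was measured in mouse bone marrow cells grown for 7 days in either of a pair of growth factors that drive macrophage formation. Cells of the first group grew with GM-CSF (granulocyte-macrophage colony-stimulating factor), were called M1 by the submitters, and were sorted as positive for CD45, MHC class II and the macrophage surface protein encoded by Adgre1, and negative for CD8a. Cells of the second group grew with M-CSF (macrophage colony-stimulating factor) supplied as 20% supernatant of L929 fibroblasts, were called M2, and were sorted as positive for CD45, the Adgre1 protein and CD11b. C57BL/6J mice were the source of the marrow. Each group had 2 arrays, 4 in all, and the deposited values ran from 1.551 to 13.947 on the log2 scale. The comparison asks how the M1 and M2 cells differ. Growth factor, the L929 supernatant that supplied M-CSF, and sort gate differed together, so their contributions were not separable. The labels do not say whether replicates were separate cultures or animals, so p-values measure only the spread between these samples. That spread may be technical for the M-CSF pair, while the GM-CSF pair differed in Xist and Y-linked genes. GM-CSF replicate 1 was the only array with Xist above background, so the sex of the cells may not be balanced between the groups. The number of arrays limits the precision.

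The M-CSF arrays lay closer together than the GM-CSF arrays. Over the 14995 genes tested, the log2 difference between the 2 M-CSF arrays had an SD of 0.1798 (Pearson r = 0.9944 across genes), and that between the 2 GM-CSF arrays an SD of 0.325 (r = 0.981). Between groups r ran from 0.9334 to 0.9533 (genes are not independent replicates). Genes at least 2-fold apart within a pair numbered 226 for GM-CSF and 7 for M-CSF. Xist, the RNA of the inactive X chromosome, and Eif2s3y, a Y-linked translation factor gene, parted GM-CSF replicate 1 from the other 3 arrays. Xist read 11.58 there and 4.93, 4.53 and 4.80 in GM-CSF replicate 2 and M-CSF replicates 1 and 2. Eif2s3y read 3.66 there and 9.10, 9.32 and 9.17 in the others. Xist and Eif2s3y were chosen after their values were seen. No sex is stated in the labels used here.

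Slc7a2, Mmp12, Fn1 and H2-M2 were among the genes that were higher in GM-CSF cells, and Cd5l, Cd55 and Ptprm among those that were lower. Of 14995 genes, 926 were higher in GM-CSF cells and 679 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 635 of these 1605 differed at least 2-fold, 445 higher and 190 lower. With arrays centred on their medians the counts were 841 higher and 865 lower. Slc7a2, a transporter of arginine and other cationic amino acids, was 46.4-fold higher (log2 difference 5.54 ± 0.11 SE, n = 2 per group, adjusted p = 3.94e-05 with limma). Acpp, an acid phosphatase gene, was 33.3-fold higher (log2 5.06 ± 0.12). Mmp12, macrophage elastase, was 30.3-fold higher (4.92 ± 0.17, adjusted p = 0.000133 with limma). Fn1, the matrix protein fibronectin, was 27.1-fold higher (4.76 ± 0.18). Plxdc2, a transmembrane protein gene, was 52.1-fold higher (5.70 ± 0.19) and Susd2, a membrane protein gene, 31.1-fold higher (4.96 ± 0.24). H2-M2, a non-classical MHC class I gene, had the largest difference, 68.2-fold (6.09 ± 0.25). Inhba, the activin A subunit, was 33.5-fold higher and Cxcl3, a neutrophil chemokine, 29.7-fold higher. In M-CSF cells the mean of H2-M2, Slc7a2, Inhba and Cxcl3 lay within the range of olfactory receptor genes, taken as background (a mean 95th percentile of 5.90), so those folds depend on the background. The same held for the M-CSF mean of Klk1b11, Il6, Nos2, Egr2, Chil3, Arg1, Socs2, Clec9a, Itgax, Olr1, Trem1 and Padi4, and for the GM-CSF mean of Cd55, Ust, Csn1s1, Folr2, Cd4, Spib and Mpo.

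Cd5l, a secreted scavenger-receptor family protein of tissue macrophages, led the genes that were lower in GM-CSF cells, at 40.4-fold (log2 difference -5.34 ± 0.13 SE, adjusted p = 3.94e-05 with limma). Cd55, which limits complement on the cell surface, was 19.6-fold lower (-4.29 ± 0.22), and Ptprm, a receptor phosphatase, 14.4-fold lower (-3.85 ± 0.24). Ust, a sulfotransferase gene, was 13.6-fold lower and Tmtc4 13.5-fold lower. Folr2, a folate receptor of macrophages, was 7.5-fold lower and Csn1s1, a casein gene, 9.05-fold lower. Slc13a3, a dicarboxylate transporter, had a difference of -4.65 ± 0.93, with 7.10 and 10.35 in the GM-CSF arrays against 13.29 and 13.45. Its difference was -3.02 without GM-CSF replicate 1 and -6.27 without GM-CSF replicate 2. Raver2 (-4.09 ± 0.69, from -2.89 to -5.30), Fcrls (-3.49 ± 0.44, from -2.75 to -4.23), Ndrg1 (-3.27 ± 0.40, from -2.59 to -3.96) and Tmem176a (-3.19 ± 0.47, from -2.38 to -3.99) moved in the same way without GM-CSF replicates 1 and 2. Klk1b11, a kallikrein family gene that probes may not part from its close paralogs, was 39.2-fold higher in GM-CSF cells, with a log2 difference of 4.05 without GM-CSF replicate 1 and 6.53 without replicate 2. These 6 genes lost their call without either M-CSF array, with adjusted p from limma of up to 0.251 for Slc13a3, 0.195 for Raver2, 0.121 for Fcrls, 0.113 for Ndrg1, 0.162 for Tmem176a and 0.136 for Klk1b11. Trended and robust variances over the 4 arrays ended these calls too, with adjusted p of 0.253 for Slc13a3, 0.196 for Raver2, 0.0964 for Fcrls, 0.089 for Ndrg1, 0.132 for Tmem176a and 0.145 for Klk1b11 (limma).

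**Figure D1:**
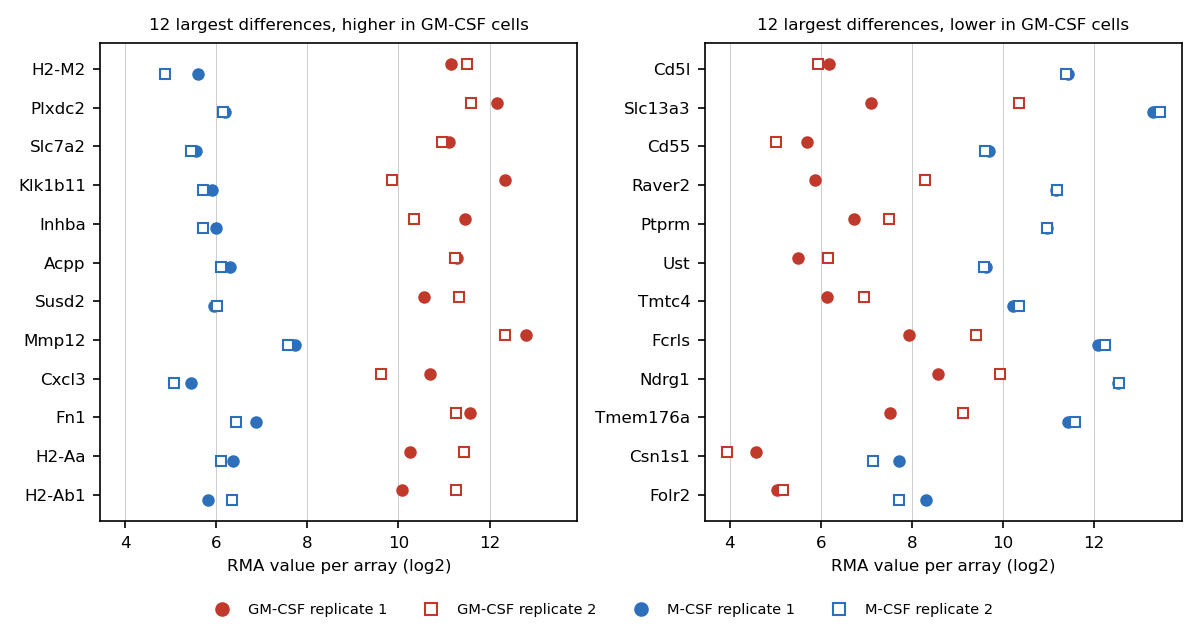
RMA values on the log2 scale per array for the 12 genes with the largest differences in each direction, with GM-CSF arrays in red and M-CSF arrays in blue, circles for replicate 1 and open squares for replicate 2. Each gene's 2 arrays of one group lie above both arrays of the other, and Slc13a3 has GM-CSF values of 7.10 and 10.35.

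The counts of called genes changed with the arrays kept. A fit without a GM-CSF array takes its spread from the closer M-CSF pair alone, so its larger count is no support for the calls. Without M-CSF replicate 1, 196 genes were higher and 65 lower, and without M-CSF replicate 2, 168 and 65, against 1468 and 1178 without GM-CSF replicate 1 and 1683 and 1522 without GM-CSF replicate 2. All 1605 called genes had both arrays of one group above both of the other, as did 55.4% of the genes tested, where chance gives 33.3%. Of the 152 genes that the naming rule picked, 103 passed. That share is fixed in part by the rule, which takes genes past the threshold and the largest differences of each list. Many of these calls were lost in the fits without an M-CSF array. Of the 35 gene lists tested, 20 were shifted higher in GM-CSF cells and 0 lower with the preset correlation of camera (fry called 15). With an estimated correlation 0 passed, in a test on 2 degrees of freedom that a list may fail whatever its correlation. The preset version takes its degrees of freedom from the number of genes, so its small p-values do not rest on many arrays.

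**Figure D2:**
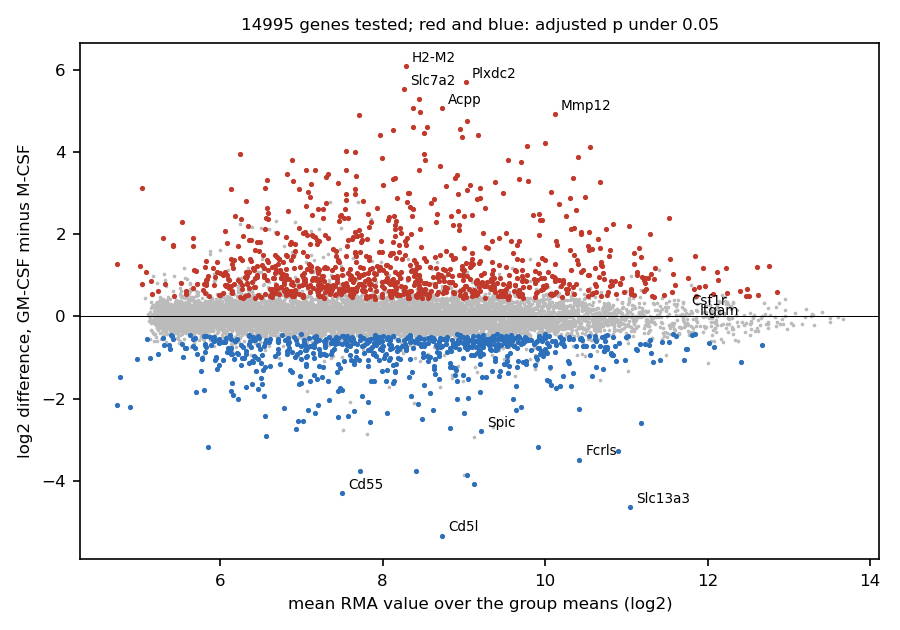
Log2 difference (GM-CSF minus M-CSF) of each of the 14995 genes tested against its mean RMA value on the log2 scale, with the genes past an adjusted p of 0.05 in red (higher) and blue (lower). The points reach from -5.34 for Cd5l to 6.09 for H2-M2.

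Several MHC class II genes were higher in GM-CSF cells. These cells were sorted for that protein, so this is not independent evidence of a difference. H2-Aa was 24.4-fold higher (log2 4.61 ± 0.36 SE), H2-Ab1 24.2-fold (4.60 ± 0.39) and H2-Eb1 7.85-fold (2.97 ± 0.40), and Cd74, the chain that guides class II through the cell, 13.9-fold (3.79 ± 0.17). Without GM-CSF replicates 1 and 2, the log2 difference was 5.21 and 4.01 for H2-Aa, 5.19 and 3.999 for H2-Ab1 and 3.60 and 2.34 for H2-Eb1. H2-Eb1 lost its call without M-CSF replicates 1 and 2 (limma, adjusted p = 0.131 and 0.0996) and with trended and robust variances (0.0937). Of the 15 measured members of the class II presentation list, 9 were higher, 1 lower and 5 did not pass, and 11 were higher and 1 lower adjusted over the list alone. The member that was lower was Cd83 (-1.58), a surface marker of activated antigen-presenting cells, named after its value was seen, with adjusted p from limma of up to 0.0849 without an M-CSF array. The list was shifted higher (camera, adjusted p = 1.72e-06) and did not pass with an estimated correlation (adjusted p = 0.291 with an estimated correlation). With GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 left out in turn, 12, 9, 3 and 3 members were higher and 1, 1, 0 and 0 lower. Of the 7 gate genes, the 3 class II genes were higher and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0656, and adjusted p = 0.538 with an estimated correlation). The gate list passed camera with no filter (adjusted p = 0.027), with the replicate block (0.0272) and with array weights (0.0481). It also passed without GM-CSF replicates 1 and 2 (0.000195 and 0.0184) and without M-CSF replicate 2 (0.0498). Ptprc, which encodes CD45, differed by -0.07 ± 0.13, Adgre1 by -0.30 ± 0.13, Itgam (CD11b) by -0.07 ± 0.10 and Cd8a by 0.02 ± 0.17, with Cd8a in both groups within the background range. Adgre1 differed by -0.15 without GM-CSF replicate 1 and -0.44 without replicate 2.

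Several classical activation genes were higher in GM-CSF cells. Il1a, an interleukin-1 cytokine, was 17.8-fold higher (log2 4.15 ± 0.34 SE), Il6 13.9-fold (3.80 ± 0.25), Ccl5 9.57-fold (3.26 ± 0.18) and Il1b 6.62-fold (2.73 ± 0.12, adjusted p = 0.000159 with limma). Nos2, inducible nitric oxide synthase, was 8.20-fold higher (3.04 ± 0.30) and lost its call without M-CSF replicate 1 (adjusted p = 0.06 with limma) and replicate 2 (0.0745). Of 23 members, 12 were higher, 0 lower and 11 did not pass, against 16 and 1 adjusted over the list alone. The list was shifted higher (camera, adjusted p = 1.18e-09, and adjusted p = 0.291 with an estimated correlation). In fits without GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn, 16, 13, 8 and 7 members were higher and 0, 1, 0 and 0 lower. The interleukin-1 and inflammasome list had 9 of 18 members higher, 1 lower and 8 that did not pass, with 11 and 2 adjusted over the list alone, and Nlrp3, an inflammasome sensor, was 2.84-fold higher (1.504 ± 0.12). Camera gave an adjusted p of 1.72e-06 for it (adjusted p = 0.355 with an estimated correlation), and 11, 12, 3 and 3 members were higher and 1, 2, 0 and 0 lower without the arrays in the same order.

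Several alternative activation genes were also higher in GM-CSF cells. Egr2, a transcription factor, was 11.8-fold higher (log2 3.56 ± 0.27 SE), Arg1, arginase 1, 11.7-fold (3.56 ± 0.19, adjusted p = 0.000326 with limma), and Clec7a, the beta-glucan receptor dectin-1, 10.9-fold (3.44 ± 0.21). Chil3, a chitinase-like protein, was 11.8-fold higher (3.56 ± 0.36) and lost its call without M-CSF replicates 1 and 2 (adjusted p = 0.0596 and 0.0772 with limma). Of 22 members, 11 were higher, 2 lower and 9 did not pass, with 12 and 3 adjusted over the list alone. The members that were lower were Folr2 and Il4ra, the interleukin-4 receptor (-0.85, named after its value was seen, with adjusted p of up to 0.122 without an M-CSF array, limma). Mrc1, the mannose receptor, did not pass (0.34 ± 0.54), with 10.54 and 8.68 in GM-CSF cells and 9.34 and 9.21 in M-CSF cells. Its difference was -0.59 without GM-CSF replicate 1 and 1.27 without replicate 2, so its direction depended on the GM-CSF array kept. Camera gave an adjusted p of 3.61e-05 (adjusted p = 0.355 with an estimated correlation, and fry adjusted p = 0.0522). Leaving out GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn gave 12, 16, 5 and 3 members higher and 5, 3, 1 and 1 lower.

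Several chemokines and chemokine receptors were higher in GM-CSF cells. Besides Cxcl3 and Ccl5, Cxcl2, another neutrophil chemokine, was 4.45-fold higher (log2 2.15 ± 0.17 SE). Of 21 chemokines, 11 were higher, 0 lower and 10 did not pass, with 13 and 0 adjusted over the list alone (camera, adjusted p = 1.2e-07, and adjusted p = 0.291 with an estimated correlation). Ccl17 differed by 2.77 ± 1.14 without passing, from GM-CSF values of 10.74 and 6.74. Its difference was 0.78 without GM-CSF replicate 1 and 4.77 without replicate 2. Ccr2, the receptor that guides monocytes, was 7.99-fold higher (2.997 ± 0.33), Cmklr1, the chemerin receptor, 3.16-fold (1.66 ± 0.13) and Cxcr4 2.84-fold (1.503 ± 0.12). Of 12 receptors, 6 were higher, 1 lower and 5 did not pass, with 8 and 2 adjusted over the list alone (camera, adjusted p = 0.000401, and adjusted p = 0.291 with an estimated correlation). The receptor that was lower was Cxcr3 (-0.76), named after its value was seen, with adjusted p from limma of 0.225 without M-CSF replicate 1 and 0.107 without replicate 2. Without GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn, 13, 13, 3 and 3 chemokines and 9, 7, 3 and 4 receptors were higher. The lower ones then numbered 0, 1, 0 and 0 and 2, 1, 0 and 0.

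Csf2rb and Csf2ra, genes of the GM-CSF receptor, were higher in GM-CSF cells and the M-CSF receptor gene did not pass. Csf2rb was 3.99-fold higher (log2 1.996 ± 0.20 SE) and Csf2ra 2.19-fold (1.13 ± 0.11). Csf2rb2, a beta chain of the mouse interleukin-3 receptor and not of the GM-CSF receptor, was 5.46-fold higher (2.45 ± 0.18). Csf2rb lost its call without M-CSF replicates 1 and 2 (limma, adjusted p = 0.0766 and 0.0772), as did Csf2ra (0.0612 and 0.0565), and the close paralogs Csf2rb and Csf2rb2 may not be parted by their probes. Csf1r differed by 0.16 ± 0.15. Socs2, a target of STAT5, was higher by 3.13 ± 0.70, with 9.33 and 6.91 in the GM-CSF arrays, and its difference was 1.92 without replicate 1 and 4.34 without replicate 2. It lost its call without M-CSF replicates 1 and 2 (adjusted p = 0.307 and 0.262 with limma), with trended and robust variances (0.277), with no filter (0.0512), after quantile normalization (0.052) and with probe set means (0.0711). Cish, another STAT5 target, did not pass (2.13 ± 0.73), with 0.88 without GM-CSF replicate 1 and 3.39 without replicate 2. Of the list's 20 members 7 were higher, 2 lower and 11 did not pass, with 11 and 3 adjusted over the list alone (camera, adjusted p = 0.000165, and adjusted p = 0.291 with an estimated correlation). Il2ra (-1.43) and Csf3r (-0.86), cytokine receptor genes named after their values were seen, were the lower ones, with adjusted p from limma of up to 0.127 and 0.198 without an M-CSF array. Leaving out GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn gave 9, 10, 2 and 1 members higher and 3, 3, 0 and 0 lower.

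Several dendritic cell genes were higher in GM-CSF cells. Itgax, which encodes CD11c, was 23.0-fold higher (log2 4.53 ± 0.23 SE, adjusted p = 0.000289 with limma) and Traf1, a signalling adaptor, 5.49-fold (2.46 ± 0.15). Clec9a, a receptor for dead cells, was 5.43-fold higher (2.44 ± 0.24) and lost its call without M-CSF replicates 1 and 2 (adjusted p = 0.0603 and 0.0742 with limma). Zbtb46 and Flt3, a transcription factor and a growth factor receptor of dendritic cells, did not pass (0.25 ± 0.14 and -0.32 ± 0.14). Flt3 lay within the background range in both groups and differed by -0.16 without GM-CSF replicate 1 and -0.47 without replicate 2. Zbtb46 lay just above that range, with means of 6.17 in GM-CSF and 5.92 in M-CSF cells. Zbtb46 differed by 0.40 without GM-CSF replicate 1 and 0.09 without replicate 2. At such levels neither gene tells much about dendritic cells. Of 24 members, 9 were higher, 1 lower (Bcl11a, -1.45, a transcription factor named after its value was seen, with adjusted p = 0.066 without M-CSF replicate 2) and 14 did not pass, with 12 and 1 adjusted over the list alone (camera, adjusted p = 1.79e-05, and adjusted p = 0.291 with an estimated correlation). With GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 left out in turn, 13, 13, 4 and 4 members were higher and 1, 2, 1 and 0 lower. Of 28 macrophage core genes, 4 were higher, 4 lower and 20 did not pass, with 5 and 6 adjusted over the list alone (camera, adjusted p = 0.672, and adjusted p = 0.806 with an estimated correlation). Axl, a receptor for dying cells, was 9.72-fold higher (3.28 ± 0.13) and Cd14, a co-receptor for bacterial lipopolysaccharide, 3.16-fold higher (1.66 ± 0.11), while C1qc, a complement C1q chain, was 2.17-fold lower (-1.12 ± 0.25). C1qc lost its call without M-CSF replicates 1 and 2 (limma, adjusted p = 0.278 and 0.274), with trended and robust variances (0.0966) and after quantile normalization (0.0539). Its difference was -0.72 without GM-CSF replicate 1. Leaving out the arrays in the same order gave 5, 8, 2 and 2 core genes higher and 5, 8, 0 and 0 lower.

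**Figure D3:**
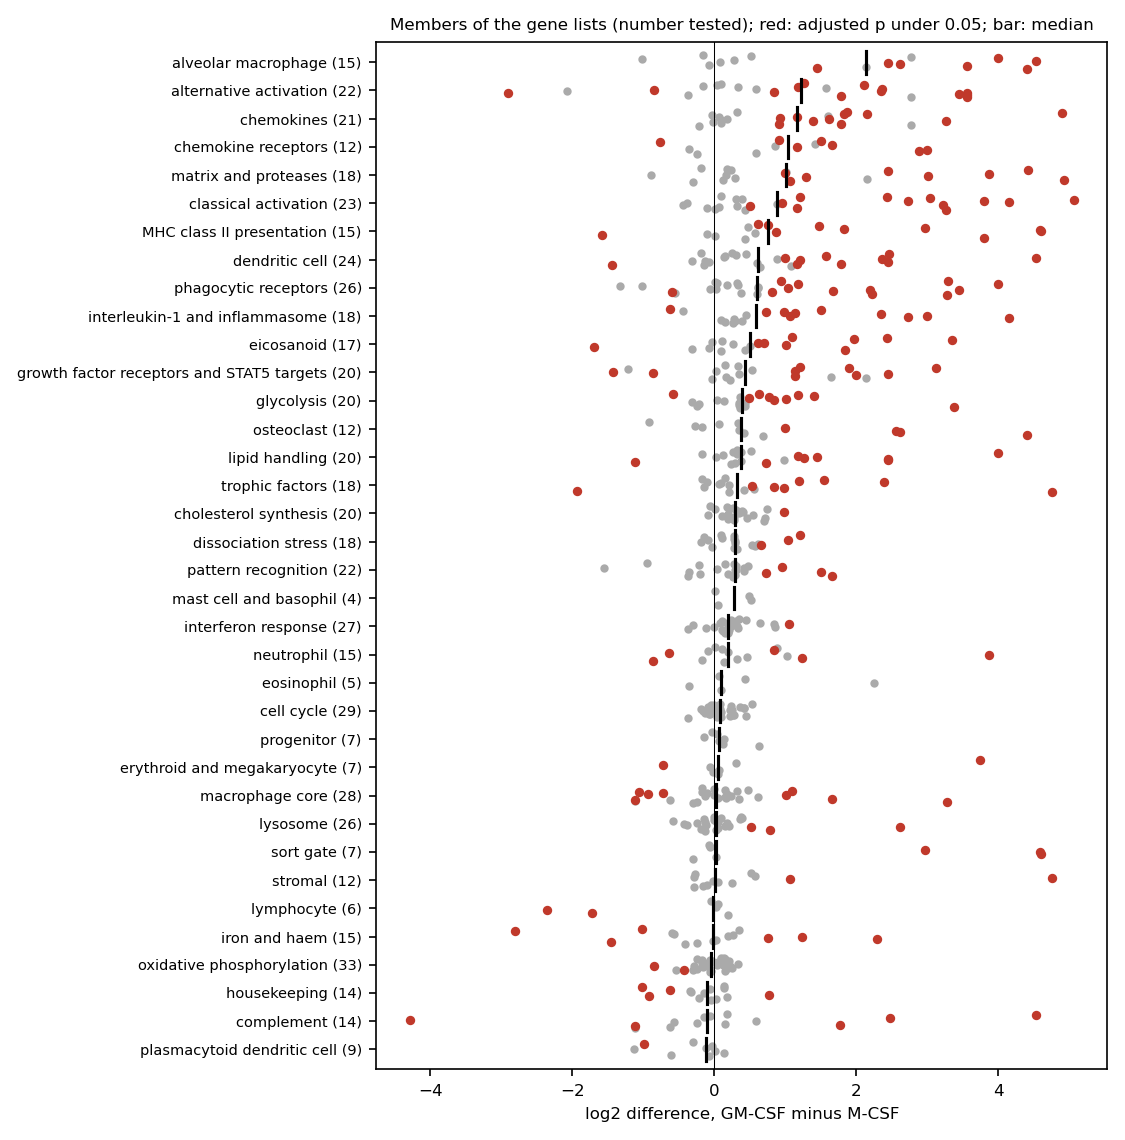
Log2 difference (GM-CSF minus M-CSF) of each measured member of the 36 gene lists, 1 line per list with the number tested, red points past an adjusted p of 0.05 and the median as a black bar. Medians run from -0.11 for plasmacytoid dendritic cell genes to 2.14 for alveolar macrophage genes.

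Some genes of the phagocytic receptor, lipid handling, alveolar macrophage and osteoclast lists were higher in GM-CSF cells. Olr1, a receptor for oxidised lipoprotein, was 15.9-fold higher (log2 3.99 ± 0.23 SE) and Trem1, an activating receptor, 9.79-fold (3.29 ± 0.12). Fabp4, a fatty acid binding protein, was 5.46-fold higher (2.45 ± 0.17), Dgat2, a triglyceride synthesis enzyme, 5.46-fold (2.45 ± 0.14) and Lpl, lipoprotein lipase, 2.71-fold (1.44 ± 0.12). Of 26 phagocytic receptors, 11 were higher, 1 lower and 14 did not pass, with 13 and 2 adjusted over the list alone (camera, adjusted p = 1.78e-06, and adjusted p = 0.291 with an estimated correlation). The 20 lipid handling genes had 7 higher, 1 lower and 12 that did not pass, with 10 and 1 adjusted over the list alone (camera, adjusted p = 1.78e-06, and adjusted p = 0.291 with an estimated correlation). The lower members were Clec4a2 (-0.60), a lectin receptor, and Apoe (-1.12), apolipoprotein E, both named after their values were seen, with adjusted p from limma of up to 0.233 and 0.103 without an M-CSF array. Of 15 alveolar macrophage genes, 7 were higher, 0 lower and 8 did not pass, with 8 and 0 adjusted over the list alone (camera, adjusted p = 2.27e-06, and adjusted p = 0.291 with an estimated correlation). Ctsk, cathepsin K, was 6.11-fold higher (2.61 ± 0.19), and it is also in the osteoclast list, where 4 of 12 members were higher, 0 lower and 8 did not pass, with 7 and 1 adjusted over the list alone (camera, adjusted p = 0.00263, and adjusted p = 0.291 with an estimated correlation). In fits without GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn, 12, 15, 7 and 6 phagocytic, 11, 11, 6 and 4 lipid, 9, 10, 5 and 5 alveolar and 6, 5, 1 and 1 osteoclast members were higher. In the same order 4, 3, 0 and 0, 2, 2, 0 and 0, 2, 1, 0 and 0, and 1, 1, 0 and 0 members were lower.

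Some matrix enzymes and growth factors were higher in GM-CSF cells as well. Besides Mmp12, Mmp2, a gelatinase, was 8.08-fold higher (log2 3.02 ± 0.13 SE, adjusted p = 0.000153 with limma) and Mmp8, a collagenase, 14.6-fold higher (3.87 ± 0.37), with adjusted p = 0.0676 without M-CSF replicate 2. Of 18 matrix and protease genes, 8 were higher, 0 lower and 10 did not pass, with 9 and 0 adjusted over the list alone (camera, adjusted p = 8.72e-06, and adjusted p = 0.291 with an estimated correlation). Tgfbi, a matrix protein induced by TGF-beta, was 5.26-fold higher (2.39 ± 0.14) and Vegfa, a vessel growth factor, 2.93-fold higher (1.55 ± 0.14). Gas6, the ligand of Axl, was 3.82-fold lower (-1.93 ± 0.33) and lost its call without M-CSF replicates 1 and 2 (limma, adjusted p = 0.192 and 0.197) and with trended and robust variances (0.093). Of 18 trophic factor genes, 7 were higher, 1 lower and 10 did not pass, with 9 and 1 adjusted over the list alone (camera, adjusted p = 0.000224, and adjusted p = 0.388 with an estimated correlation). Without GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn, 10, 10, 3 and 2 matrix and 8, 11, 3 and 3 trophic members were higher, and 1, 0, 0 and 0 and 2, 1, 0 and 0 lower.

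Some prostaglandin and glycolysis genes were higher in GM-CSF cells. The oxidative phosphorylation list was not shifted by the test. Ptges, a prostaglandin E synthase, was 10.2-fold higher (log2 3.36 ± 0.16 SE), Ptgs2, cyclooxygenase 2, 5.41-fold (2.44 ± 0.15) and Ptgir, the prostacyclin receptor, 3.93-fold (1.97 ± 0.11). Of 17 eicosanoid genes, 8 were higher, 1 lower (Hpgds, a prostaglandin D synthase named after its value of -1.70 was seen) and 8 did not pass, with 10 and 1 adjusted over the list alone (camera, adjusted p = 5.05e-05, and adjusted p = 0.355 with an estimated correlation). Aldoc, the glycolytic enzyme aldolase C, was 10.4-fold higher (3.37 ± 0.12, adjusted p = 0.000137 with limma). Of 20 glycolysis genes, 8 were higher, 1 lower and 11 did not pass, with 12 and 1 adjusted over the list alone (camera, adjusted p = 2.03e-05, and adjusted p = 0.454 with an estimated correlation, and fry adjusted p = 0.0522). The lower gene was Slc2a3 (-0.58), a glucose transporter named after its value was seen, with adjusted p from limma of up to 0.304 without an M-CSF array and 0.0619 with no filter. Of 33 oxidative phosphorylation genes, 0 were higher, 2 lower (Ndufa4, -0.85, and Cox4i1, -0.43, both of the respiratory chain, with adjusted p of up to 0.137 and 0.314 without an M-CSF array, and for Cox4i1 0.0731 with no filter) and 31 did not pass, with 0 and 1 adjusted over the list alone (camera, adjusted p = 0.599, and adjusted p = 0.837 with an estimated correlation). With GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 left out in turn, 8, 10, 3 and 3 eicosanoid and 13, 8, 2 and 1 glycolysis members were higher. Lower members numbered 1, 2, 1 and 1 for eicosanoid, 1, 3, 0 and 0 for glycolysis and 3, 3, 0 and 0 for oxidative phosphorylation genes, with 0 of the last higher in each fit.

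Iron, complement and cholesterol genes went different ways. Spic, a transcription factor of red pulp macrophages, was 6.97-fold lower in GM-CSF cells (log2 -2.80 ± 0.12 SE, adjusted p = 0.000153 with limma), and Cp, ceruloplasmin, 2.75-fold lower (-1.46 ± 0.17), a call lost without M-CSF replicates 1 and 2 (adjusted p = 0.0984 and 0.102 with limma). Of 15 iron and haem genes, 3 were higher, 3 lower and 9 did not pass, with 4 and 5 adjusted over the list alone (camera, adjusted p = 0.626, and adjusted p = 0.794 with an estimated correlation). Of 14 complement genes, 3 were higher, 2 lower and 9 did not pass, with 4 and 5 adjusted over the list alone (camera, adjusted p = 0.874, and adjusted p = 0.935 with an estimated correlation), and the median of -0.11 and the mean of 0.11 differ in sign. Cfb, complement factor B, was 5.55-fold higher (2.47 ± 0.38), with 3.11 without GM-CSF replicate 1 and 1.84 without replicate 2. Cfb lost its call without M-CSF replicates 1 and 2 (limma, adjusted p = 0.149 and 0.17) and with trended and robust variances (0.103). Mvd, an enzyme of cholesterol synthesis, was higher by 0.98 (adjusted p of up to 0.111 without an M-CSF array, limma) and 19 of that list's 20 members did not pass, with 5 higher and 0 lower adjusted over the list alone. The list was shifted higher (camera, adjusted p = 0.000153, and adjusted p = 0.527 with an estimated correlation, and fry adjusted p = 0.179). In fits without GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn, 4, 9, 0 and 0 cholesterol, 3, 6, 0 and 0 iron and 4, 3, 1 and 2 complement members were higher. Lower members numbered 0 for cholesterol in each fit, 4, 6, 1 and 1 for iron and 3, 5, 1 and 1 for complement genes.

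Interferon, pattern recognition and dissociation stress lists were shifted higher by camera, each with few members passing. Of 27 interferon response genes, Oas3, an antiviral enzyme gene, was higher by 1.05 (1.41 and 0.69 without GM-CSF replicates 1 and 2, adjusted p of up to 0.288 without an M-CSF array, 0.0677 with trended and robust variances and 0.0502 with no filter, limma), 0 were lower and 26 did not pass, with 0 and 0 adjusted over the list alone (camera, adjusted p = 0.02, and adjusted p = 0.794 with an estimated correlation, and fry adjusted p = 0.611). The list call was lost without M-CSF replicate 2 (camera, adjusted p = 0.137) and without GM-CSF replicate 2 (0.353), where the list's median was -0.10. Of 22 pattern recognition genes, 4 were higher, 0 lower and 18 did not pass, with 6 and 1 adjusted over the list alone (camera, adjusted p = 0.0122, and adjusted p = 0.533 with an estimated correlation, and fry adjusted p = 0.0791). Of 18 dissociation stress genes, 3 were higher (Socs3 1.20, Ier3 1.04 and Egr1 0.66, early response genes, with adjusted p of up to 0.0581, 0.244 and 0.235 without an M-CSF array), 0 lower and 15 did not pass, with 3 and 0 adjusted over the list alone (camera, adjusted p = 0.00637, and adjusted p = 0.527 with an estimated correlation, and fry adjusted p = 0.192). Without GM-CSF replicate 2 the pattern recognition and stress calls were lost (camera, adjusted p = 0.211 and 0.291). Without GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 in turn, 18, 3, 0 and 0 interferon, 11, 7, 2 and 2 pattern recognition and 9, 3, 1 and 0 stress members were higher. Interferon members that were lower numbered 0, 3, 0 and 0, pattern recognition members 2, 5, 0 and 0, and stress members 0 in each fit.

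Markers of other cell types were mostly not passed by the test. In the lymphocyte list 2 of 6 members were lower in GM-CSF cells, 0 higher and 4 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.111, and adjusted p = 0.527 with an estimated correlation). The list passed camera as lower without GM-CSF replicate 2 (adjusted p = 0.031) and without M-CSF replicate 1 (0.0159). The lower members were Cd79b, a B cell receptor chain, 5.14-fold lower (log2 -2.36 ± 0.13 SE), and Cd4, a co-receptor that macrophages can also carry, 3.29-fold lower (-1.72 ± 0.17), with adjusted p = 0.0596 without M-CSF replicate 1. Of 15 neutrophil genes, 3 were higher (Mmp8, Lcn2 and Padi4), 2 lower (Csf3r and Mpo) and 10 did not pass, with 4 and 2 adjusted over the list alone (camera, adjusted p = 0.0664, and adjusted p = 0.527 with an estimated correlation). The neutrophil list passed camera as higher with no filter (adjusted p = 0.0244), after centring (0.0469) and with the replicate block (0.0439). It did so too without GM-CSF replicate 2 (0.000384) and without M-CSF replicate 2 (0.0385). Padi4, Csf3r and Mpo were named after their values were seen. Without an M-CSF array the adjusted p from limma reached 0.0676 for Mmp8, 0.0537 for Lcn2, 0.175 for Padi4, 0.198 for Csf3r and 0.163 for Mpo. S100a8, an abundant neutrophil gene, did not pass (0.89 ± 0.44), with 0.14 without GM-CSF replicate 1 and 1.64 without replicate 2. Erythroid and megakaryocyte genes had 1 of 7 higher (Ppbp, a platelet chemokine, 3.75 ± 0.48, with 3.04 without GM-CSF replicate 1 and 4.45 without replicate 2), 1 lower (Gp9, -0.73) and 5 that did not pass, the same adjusted over the list alone (camera, adjusted p = 0.601, and adjusted p = 0.794 with an estimated correlation). Ppbp and Gp9 reached an adjusted p from limma of 0.116 and 0.154 without an M-CSF array, and Ppbp 0.106 with trended and robust variances. Of 12 stromal genes, 2 were higher (Fn1, and Dcn, the matrix protein decorin, by 1.06, with adjusted p of up to 0.318 without an M-CSF array, 0.0787 with trended and robust variances and 0.0591 with no filter), 0 lower and 10 did not pass, with 3 and 0 adjusted over the list alone (camera, adjusted p = 0.349, and adjusted p = 0.588 with an estimated correlation), while fry called the list (adjusted p = 0.0371). Plasmacytoid dendritic cell genes had 1 of 9 lower (Spib, a transcription factor, -0.995, with adjusted p of up to 0.136 without an M-CSF array), 0 higher and 8 that did not pass, the same adjusted over the list alone (camera, adjusted p = 0.11, and adjusted p = 0.656 with an estimated correlation). That list passed camera as lower without GM-CSF replicate 2 (adjusted p = 0.00638) and without M-CSF replicate 1 (0.0457). Of 5 eosinophil and 7 progenitor genes 0 passed, also adjusted over each list alone (limma; camera adjusted p = 0.57 and 0.566, and adjusted p = 0.806 for both with an estimated correlation), but the eosinophil list passed camera as higher without GM-CSF replicate 2 (adjusted p = 0.0384). The mast cell and basophil list had 4 tested members, too few for the set test, and 0 passed. With GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2 left out in turn, 4, 8, 1 and 0 neutrophil members were higher and 4, 2, 0 and 0 lower. Without GM-CSF replicate 2, 2 eosinophil, 2 progenitor and 2 mast cell and basophil members were higher, and without GM-CSF replicate 1, 1 eosinophil member was higher and 1 lower. Over the arrays in the same order, 3, 4, 1 and 1 stromal and 1, 1, 0 and 0 erythroid and megakaryocyte members were higher. In that order 2, 2, 1 and 2 lymphocyte, 2, 4, 0 and 0 plasmacytoid and 1, 1, 0 and 0 erythroid and megakaryocyte members were lower.

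Cell cycle, lysosome and housekeeping lists were not shifted by the test with all arrays. Of 29 cell cycle genes 0 passed in either direction, also adjusted over the list alone (limma; camera adjusted p = 0.288, and adjusted p = 0.809 with an estimated correlation), with 1, 8, 0 and 0 higher and 1, 0, 0 and 0 lower without GM-CSF replicates 1 and 2 and M-CSF replicates 1 and 2. The cell cycle list passed camera as higher without GM-CSF replicate 2 (adjusted p = 0.00504) and without M-CSF replicate 1 (0.0437). Of 26 lysosome genes, 3 were higher (Ctsk, Cd63 and Ctsh, the last pair with adjusted p of up to 0.282 and 0.279 without an M-CSF array and 0.054 and 0.0532 with no filter), 0 lower and 23 did not pass, with 3 and 1 adjusted over the list alone (camera, adjusted p = 0.57, and adjusted p = 0.806 with an estimated correlation). Without the arrays in the same order, 3, 6, 1 and 1 lysosome members were higher and 3, 1, 0 and 0 lower, and 1, 1, 0 and 0 housekeeping members were higher and 4, 3, 0 and 0 lower. Of 14 housekeeping genes, Pgk1, a glycolytic enzyme, was higher by 0.76 (adjusted p of up to 0.173 without an M-CSF array, limma), 3 were lower and 10 did not pass, with 1 and 4 adjusted over the list alone (camera, adjusted p = 0.141, and adjusted p = 0.527 with an estimated correlation). The lower ones were Tfrc, the transferrin receptor (-1.02 ± 0.12), Hprt, a purine salvage enzyme (-0.93 ± 0.12), and Rps18, a ribosomal protein (-0.63 ± 0.13), and 0 of these 3 passed without M-CSF replicate 1 or replicate 2.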

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

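Array weights per group were chosen after seeing the data, and the other alternatives were planned. Leaving out each array in turn gave 168 to 1683 genes higher, 65 to 1522 lower and 233 to 869 at least 2-fold apart, 44 to 201 list members higher and 6 to 63 lower (127 and 30 with all arrays), and 21 lists higher in each fit and 0 to 2 lower. Without an M-CSF array the spread came from the wider GM-CSF pair alone, with 1 residual degree of freedom fewer. Without a GM-CSF array it came from the closer M-CSF pair alone. Those fits take no account of the spread between the GM-CSF arrays, so their calls are too many to rely on. With the dim filter applied again to the 3 arrays left, the counts of higher and lower genes were 1476 and 1231 without GM-CSF replicate 1, 1721 and 1616 without GM-CSF replicate 2, 188 and 55 without M-CSF replicate 1, and 151 and 52 without M-CSF replicate 2. Higher genes were 57.7% of the calls, 56.7% after quantile normalization and 49.3% after centring. An adjusted p of 0.01 gave 438 higher and 223 lower. The unmoderated statistic gave 0 higher, 1 lower and 0 at least 2-fold apart (limma gave 3821 genes and the unmoderated statistic 2518 at an unadjusted p under 0.05). With an estimated correlation 0 lists were higher, and fry called 15, adding the stromal list and ending the calls of alternative activation, cholesterol synthesis, interferon response, pattern recognition, glycolysis and dissociation stress. Of the 1605 called genes, 1328 were also called with no filter, 1534 with the stricter filter, 1521 after quantile normalization, 1520 after centring, 1567 with probe set means, 1512 with trended and robust variances and 1605 with array weights, each in the same direction. Of the calls of genes named in the text, trended and robust variances ended 14, no filter 7 (Cd63, Cox4i1, Ctsh, Dcn, Oas3, Slc2a3, Socs2), quantile normalization 3 (C1qc, Dcn, Socs2), centring 2 (Cd63, Dcn), the replicate block 2 (Cox4i1, Ctsh), probe set means 1 (Socs2) and the stricter filter and array weights 0. Leaving out either M-CSF array ended many more of these calls than any of those settings. The deviations of same-numbered arrays correlated at 0.0649 over genes, so the numbers were not taken as pairs, and the replicate block called 1640 genes, 1448 of them shared. Values changed sign for the interferon response list (-0.101 without GM-CSF replicate 2, up to 0.491 without GM-CSF replicate 1) and Mrc1 (-0.591 without GM-CSF replicate 1, and 1.269 without GM-CSF replicate 2). They also did so for Ptprc (0.045 without GM-CSF replicate 1, down to -0.182), Csf1r (-0.009 without GM-CSF replicate 2, up to 0.337) and Mgl2 (-0.226 without GM-CSF replicate 1, up to 3.377). Cd8a changed sign as well (-0.021 after centring, -0.175 to 0.22 without an array, with -0.175 without GM-CSF replicate 2 and -0.096 without M-CSF replicate 1). For these the cause was not tested. Genes within the olfactory receptor range in 1 group have folds limited by background.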

Other observations

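The gene families, patterns and explanations tested here were all chosen after the values were seen. The limma fits and other normalizations quoted with them were planned. Over 234 families of genes that share a symbol stem (at least 8 members each), 7 passed the camera test and 0 with an estimated correlation (adjusted p = 0.999 for each of the 7). Of these, Cxcl (6 of 12 higher, 0 lower, median 1.04, 0.91 to 1.13 without each array, camera adjusted p = 0.000349) and Mmp (5 of 15 higher, 0 lower, median 0.28, 0.09 to 0.47, camera adjusted p = 0.0115) overlap lists already described. Of 34 Rpl genes, which encode ribosomal proteins, 11 were lower, 0 higher and 32 had a difference below 0, with a median of -0.35 (-0.39 to -0.33 without each array), and of 30 Rps genes, 11 were lower, 0 higher and 28 lay below 0, with a median of -0.33 (-0.48 to -0.31). The medians were -0.35 and -0.34 after quantile normalization and -0.39 and -0.37 after centring. Camera gave adjusted p of 5.82e-08 and 3.58e-07 over the families. The small nucleolar RNA families shifted lower by the same test with few members passing. Snord had 3 of 25 genes lower, 0 higher and a median of -0.33 (-0.35 to -0.23 without each array; camera, adjusted p = 0.00228), and Snora 1 of 19 lower (0 after quantile normalization), 0 higher and a median of -0.44 (-0.59 to -0.30; 0.0194). Part of the Snora shift came from GM-CSF replicate 1, where 13 of 19 read lower than in replicate 2 (12 of 25 for Snord). Of 9 Slfn genes, which encode schlafen proteins, Slfn4 (9.70-fold) and Slfn1 (7.95-fold) were higher in GM-CSF cells and 0 lower. The family median was 0.41 (camera, adjusted p = 0.0194), with 0.75 without GM-CSF replicate 1 and 0.11 without GM-CSF replicate 2. Much of that shift came from GM-CSF replicate 2, as 9 of 9 read lower in replicate 1.

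Xist and Y-linked genes part GM-CSF replicate 1 from the other 3 arrays, and 3 of the 9 Y-linked genes on the array, Eif2s3y, Uty and Kdm5d, lay far lower there. Uty read 3.58 in GM-CSF replicate 1 and 8.68, 8.93 and 8.84 in the others, Kdm5d 4.68 against 7.64, 8.04 and 7.91, and Srsy, less clearly parted, 5.29 against 6.05, 6.36 and 7.03. All 4 arrays had either Xist alone or these 4 Y-linked genes alone above the olfactory receptor range, consistent with female cells in GM-CSF replicate 1 and male cells in the others. Arrays with both numbered 0, which argues against cells of both sexes pooled in an array. The GM-CSF arrays would then come from different animals, so their spread may not be purely technical; how much of it goes with sex the design cannot test.

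Many genes of the M-CSF cells, though not all, were higher in GM-CSF replicate 2 than in GM-CSF replicate 1. This held for 434 of the 679 genes called lower in GM-CSF cells (63.9%) and 40.3% of the 926 called higher. Of all genes tested, 56% read higher in replicate 2. A call favours genes with a small spread between replicates. Among the 223 genes with a mean at least 2-fold lower in GM-CSF cells, 153 (68.6%) read higher in replicate 2. Slc13a3 read 10.35 against 7.10 and Cd300e, which did not pass (limma, adjusted p = 0.105, log2 difference -1.23 without GM-CSF replicate 1 and -4.17 without replicate 2), 9.48 against 6.54, while Cd5l was lower in replicate 2 (5.93 against 6.19), as were Ccl17 (6.74 against 10.74) and Mgl2 (5.87 against 9.47), which are not genes of the M-CSF cells. M-CSF type cells or their RNA mixed into replicate 2 would imply a similar share for each gene, but of 53 genes low in replicate 1 and high in M-CSF cells 19 implied a share under 0.05 and 21 over 0.2 (median 0.143, quartiles 0.037 and 0.393), which argues against it as the whole cause. The low replicate 1 values that picked these genes also enter the shares, which may favour high ones. Genes over 0.2 included small RNAs such as Rnu12 (1.076) and Snord104 (0.724) beside protein-coding genes such as Pltp (0.928). A different content of dendritic cells stays open. The dendritic cell list had a median difference of 0.077 (replicate 1 minus replicate 2), with 15 of 24 members higher in replicate 1. That lay at the 98.7th percentile of 10000 random lists matched on level. The 926 genes called higher in GM-CSF cells had a median of -0.077 for replicate 2 minus replicate 1. Lists matched on level alone cannot part dendritic cells from that wider difference. The gate for the Adgre1 protein and against CD8a would also remove some dendritic cells. The sex of the cells also stays open, as 1 of the 2 GM-CSF arrays carried Xist and no other array of that group could be set beside it.

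Cd79b, Bank1 and Fcrl1, known from B cells, were higher in M-CSF cells (log2 differences of -2.36, -2.31 and -2.35, M1 minus M2), though Bank1 had an adjusted p from limma of 0.0579 without M-CSF replicate 1 and 0.0507 without replicate 2. B cells among the sorted M-CSF cells might bring their other abundant transcripts, but 13 other B cell markers had a median difference of -0.079 (SD 0.156, lowest -0.38 for Ms4a1) and 9 lay within the olfactory receptor range in M-CSF cells, including Cd79a at 4.61. This argues against B cells, which the gate on the Adgre1 protein and CD11b would also remove. Expression of these genes by the M-CSF macrophages themselves remains a hypothesis that the arrays do not test.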
